A study of Trypanosoma brucei with 16 samples.

How the data were processed

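Gene expression was measured by RNA sequencing in Trypanosoma brucei, in bloodstream forms (BSF, the single marker line, grown at 37 °C) and in procyclic forms (PCF, the insect stage, a separate line, grown at 28 °C). Each stage was left untreated or exposed for 18 h to 1 of 3 ligands of G-quadruplexes, folded structures of guanine-rich nucleic acids: AQ1, Pt-TTPY (spelled pT_TTPY in the labels) and pyridostatin. Each of the 8 groups held 2 libraries, 16 in all. The labels give the treatment as 2 times the IC50, and the doses in µM as 0.24 for AQ1, 0.26 for Pt-TTPY and 11.04 for pyridostatin in BSF, and as 48.46 for Pt-TTPY and 18.18 for pyridostatin in PCF. The AQ1 dose in PCF was given as 9 without a unit, and the labels do not settle whether these values are the IC50 or already 2 times it. The labels say that samples were taken in duplicate, not that the duplicates were separate cultures, and stage could not be separated from cell line, medium and temperature.

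The deposited values were counts of reads per annotated feature, made by the authors. Per the labels' protocols, ribosomal RNA was depleted with a kit made for bacteria, reads of 100 bases were single-ended at an intended depth of 10 M reads, quality was checked with FastQC 0.11.9 and reads were aligned with STAR 2.7.10b. The labels name a directional RNA library kit in one place and a DNA library kit in another. Per the file headers, reads were counted with featureCounts 2.0.4 (the labels say 2.0.1) on exons grouped by gene, with reads assigned to the annotated strand and multi-mapping reads counted at every alignment, in the TbruceiLister427_2018 annotation of TriTrypDB release 63 (contigs of build Tb427v10). The libraries held 3411592 to 11894770 counts. Copies of a repeated gene share reads, and a call on one copy is not independent of the others. Whether the strand setting suits the kit used was not settled, and with a kit of the opposite orientation the counts would be of antisense reads.

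The counts covered 17243 features, 5283 of them pseudogenes, and 98.5% had a coding length that is a multiple of 3, so most models hold no untranslated regions. Features whose length is no multiple of 3 (266) are called non-triplet features below. None of the feature IDs matched the 10221 genes named in the reference of another strain, so features are given by ID and position, and 50 lists and single genes chosen by product or identifier were void. A planned list of genes with a potential G-quadruplex motif was not tested because no genome sequence of this strain was at hand.

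Features were grouped by contig: 208 on the 13 contigs of bloodstream expression sites (BES, the telomere-proximal units that carry variant surface glycoprotein genes), 6208 on subtelomeric contigs, 8712 on chromosome cores and 2115 on unassigned contigs. These contig groups, the comparisons, the tests, the alternatives and the rule for naming features were fixed before the data were examined. Smaller groups were made afterwards from coordinates and lengths: the 19 features upstream on BES1, the 176 upstream features and 12 terminal features of the other expression sites, 2552 intact subtelomeric features and 3656 subtelomeric pseudogenes, 364 core pseudogenes, 453 copies in core tandem arrays, and the first and last 3 features (348 each) of the 116 core units, defined as runs of at least 10 features on 1 strand. The core of each of the chromosomes 1 to 11 was also tested as a group.

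Ligand effects, and differences between ligands, were tested per stage with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on counts as deposited, with TMM normalization, robust dispersions and features passing filterByExpr with a minimum count of 10 (10727 in BSF and 9567 in PCF). Stage and the difference of a ligand response between stages were tested in a fit of all 16 libraries (10713 features). Calls were features with a Benjamini-Hochberg adjusted p under 0.05. Groups of features were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Log2 fold changes are given with their standard error (SE), and values per group as CPM (counts scaled to a common library total) with the standard deviation (SD, n = 2). On simulated counts with 100 features changed per fold size, made with the spread of the fit of all 8 libraries of a stage, the BSF pyridostatin test recovered 2% of log2 changes of 1 and 60% of changes of 2, and the PCF pyridostatin test 3% and 55%. With the smaller spread found without untreated replicate 1, the same tests of 8 libraries recovered 78% and 100% in BSF and 91% and 100% in PCF.

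Named features were at most 2 per direction, those with the greatest change among calls with a mean of at least 10 CPM in the higher group and no overlap of the libraries of both groups. The rule as fixed also asked for a product name, which could not be applied. Folds against a group with no counts are lower bounds, computed at a floor of 3 counts over the group. Intervals are exact 95% intervals and cover counting error only.

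Because the first untreated library of each stage stood far from all others, every count was also computed with untreated replicate 1 left out. For the ligand effects leaving out each library was chosen before the data were seen, and for the other comparisons it was chosen after seeing the data, as was naming features in that fit. The lone untreated library is then assumed to vary like the other groups. On simulated counts this smaller fit recovered 51% of log2 changes of 1 and 100% of changes of 2 for pyridostatin in BSF, and 71% and 99% in PCF.

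Other alternatives were DESeq2 1.42.0, relative log expression size factors, no count filter or a filter of 5 CPM in 2 libraries, only the groups compared or all 16 libraries in the fit, the replicate number as a block, and leaving out non-triplet and expression-site terminal features. Correlations of fold changes between ligands were set beside 100 simulations of unchanged groups against the same untreated libraries, and were computed again among features with a mean of at least 10 CPM. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and data.table (version 1.17.8).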

Results

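RNA sequencing covered 16 libraries of Trypanosoma brucei, 2 for each of 8 groups made of life stage (BSF or PCF) and treatment (none, AQ1, Pt-TTPY or pyridostatin). The comparisons ask which transcripts each ligand changed in each stage, how the ligands differed from each other, and whether the response depended on the stage. The PCF libraries held 11894770 and 5397131 counts without treatment, 4414777 and 4442351 with AQ1, 4527923 and 4880903 with Pt-TTPY, and 3411592 and 4422687 with pyridostatin. The BSF libraries held 9146848 and 6001848 counts without treatment, 5644498 and 3488685 with AQ1, 6874733 and 5917849 with Pt-TTPY, and 5932459 and 5988349 with pyridostatin. No replicate pair was closer than counting error allows. As the duplicates were not described as separate cultures, p-values measure only the spread between these libraries, which may be technical.

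Untreated replicate 1 of both stages stood apart from every other library. Non-triplet features took 56.4% of its counts in PCF and 47.8% in BSF, against 0.978% to 3.39% in the other 14 libraries. A family of 13 features of 2246 to 2251 nt alone took 37.9% in PCF and 33.9% in BSF. The rank correlation across features (which are not independent replicates) of the 2 untreated libraries was 0.744 in PCF and 0.71 in BSF, against 0.956 to 0.982 in the treated groups. The biological coefficient of variation was 0.326 in BSF and 0.315 in PCF, and 0.154 and 0.118 with untreated replicate 1 left out. Because this library enters every comparison with untreated cells, counts are given with and without it. With replicate 2 left out instead, so that replicate 1 alone stood for untreated cells, each ligand was assigned 4151 to 4924 changed features in BSF and 4270 to 5395 in PCF.

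**Figure D1:**
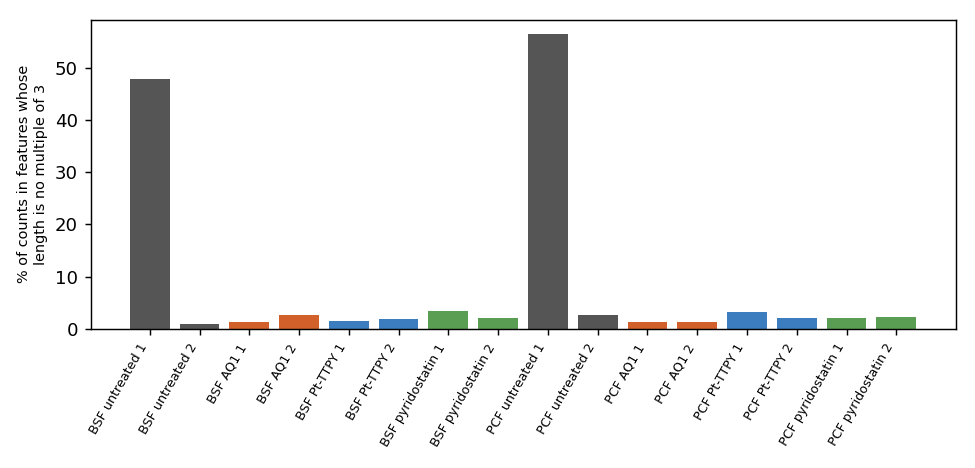
Share of counts (percent, bars from 0) on non-triplet features in each of the 16 libraries. Non-triplet features held 56.4% and 47.8% of the counts of untreated replicate 1 of PCF and BSF and at most 3.39% of those of any other library.

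Between the untreated stages, the transcripts of the expression sites were far lower in PCF than in BSF. Of 169 measured features on expression-site contigs, 145 were lower in PCF (154 adjusted over the list alone) and none was higher, with a median log2 fold change of −6.11. The 19 features upstream on BES1 had a median of −8.34 (18 lower), the upstream features of the other expression sites −6.04 (121 of 139 lower), and their terminal features −4.49 (5 of 10 lower). Reads aligning to several sites were counted at each, so the upstream results of BES1 and of the other sites are not independent. The feature nearest the end of BES1, Tb427_000016000 (75570 to 77000), lay at the place where the variant surface glycoprotein gene of an expression site is found. It reached 7209.7 and 125883.39 CPM in the untreated BSF libraries and 0.84 and 70.59 CPM in the PCF libraries (log2 fold change −10.77 ± 1.77 SE, adjusted p = 0.00145). The pseudogene before it, Tb427_000015900:pseudogene (69440 to 70855), had 1687 counts in BSF and 0 in PCF and was at least 642-fold lower in PCF.

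Subtelomeric features were also lower in PCF, with a median log2 fold change of −1.68, 229 of 712 lower and 2 higher (269 and 3 adjusted over the list alone). Subtelomeric pseudogenes had a median of −1.86 (127 lower) and intact subtelomeric features −1.52 (102 lower, 2 higher). On unassigned contigs 346 of 1320 features were lower and 3 higher (453 and 3 adjusted over the list alone), with a median of −1.15. Core features went both ways with all libraries, with 560 higher and 506 lower of 8512 (448 and 457 adjusted over the list alone) and a median of 0.12. Without untreated replicate 1 of both stages the higher ones prevailed, with 1508 higher and 717 lower core features (median 0.23), while 25 subtelomeric features were higher and 301 lower and 50 and 523 on unassigned contigs. The medians of the 11 chromosome cores lay between −0.12 (chromosome 2) and 0.20 (chromosome 10). Tb427_060008400 (Chr6_core, 132152 to 132541) was higher in PCF by 7.67 ± 1.22, at 630.87 and 14504.74 CPM against 4.59 and 77.98 in BSF (adjusted p = 0.00118). Tb427_100109300 (Chr10_core, 2512753 to 2513190) was higher by 7.45 ± 1.14, at 1169.51 and 26203.55 CPM against 14.21 and 155.95 (adjusted p = 8.92e-04).

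The edgeR test called 565 features higher and 1226 lower in PCF of 10713, and 1583 and 1690 with untreated replicate 1 of both stages left out. A fit of only the untreated libraries called 0 higher and 147 lower. Of the 1791 features called with all libraries, 1645 were also called without untreated replicate 1, and all 1791 had the same sign in both. The group tests gave adjusted p = 8.57e-124 for expression-site contigs, 3.43e-19 for subtelomeric contigs, 4.14e-16 for unassigned contigs and 3.75e-38 for core contigs. With an estimated correlation these were adjusted p = 2.49e-04, 0.00891, 0.00891 and 1.09e-06, and the terminal features of the other expression sites were not called (adjusted p = 0.249 with an estimated correlation). The call of those terminal features was also lost without BSF untreated replicate 2 (adjusted p = 0.164). The subtelomeric median was −2.96 without PCF untreated replicate 1 and −1.10 without BSF untreated replicate 1, and the core median 0.05 without PCF untreated replicate 2 and 0.23 without BSF untreated replicate 1. Stage is confounded with cell line, medium and temperature.

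**Figure D2:**
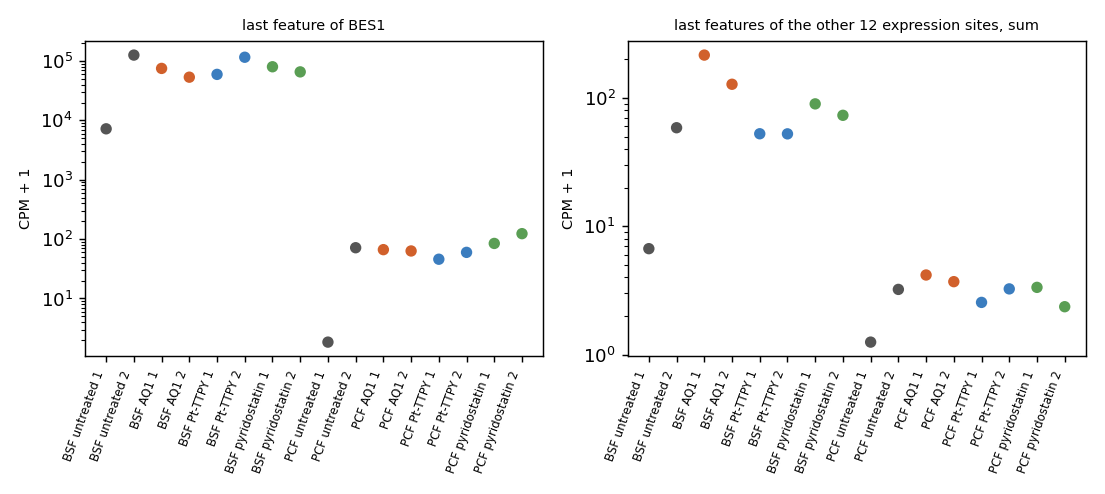
CPM (log axis, with 1 added) of the BES1 terminal feature and of the summed terminal features of the other 12 expression sites, 1 point per library. The BES1 terminal feature lay between 7209.7 and 125883.39 CPM in BSF and between 0.84 and 122.55 CPM in PCF.

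In BSF, AQ1 went with a higher median of the terminal features of the expression sites other than BES1 and a lower one of BES1 upstream features, calls that rested on the preset correlation. The summed level of the 12 terminal features of the sites other than BES1 was 215.08 and 126.98 CPM with AQ1 (mean 171.03, SD 62.29, n = 2), against 5.69 and 57.65 CPM without treatment. Their median log2 fold change was 1.67, and it was 1.05 with untreated replicate 1 left out (adjusted p = 3.89e-13 and 3.34e-05). Features upstream on BES1 were lower, with a median of −0.63 (adjusted p = 3.63e-06). With an estimated correlation neither was called (adjusted p = 0.168 with an estimated correlation and 0.158 with fry for both). The BES1 terminal feature itself, at 75073.46 and 53420.13 CPM with AQ1, did not pass the test (log2 fold change −0.36 ± 1.12, and −1.19 ± 0.46 with untreated replicate 1 left out, adjusted p = 0.298). Among the regions, subtelomeric contigs had a median of 0.17 (adjusted p = 3.19e-05) and unassigned contigs 0.14 (adjusted p = 0.002), with adjusted p = 0.168 and 0.194 with an estimated correlation. Core contigs had a median of −0.03 (adjusted p = 4.12e-04, and 0.014 with an estimated correlation) and expression-site contigs −0.29 (adjusted p = 0.0753). Without BSF untreated replicate 2 the subtelomeric, core, unassigned and BES1 upstream calls were lost (medians 0.01, 0.01, 0.15 and −0.31, adjusted p = 0.594, 0.594, 0.631 and 0.0824) and the terminal median was 3.25. Without AQ1 replicate 1 the terminal, subtelomeric and unassigned medians were 0.96, 0.06 and 0.06, and without untreated replicate 1 the subtelomeric and unassigned ones 0.50 and 0.22.

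No single feature passed the edgeR test for AQ1 in BSF with all libraries (10727 tested, 883 at an unadjusted p under 0.05), and DESeq2 called 24 higher and 51 lower. Adjusted over the list alone, 2 features on expression-site contigs were higher and 2 lower, and 4 subtelomeric features were higher. Once untreated replicate 1 was left out, 7 features were higher and 2 lower. Tb427_000005900, the terminal feature of BES10 (37132 to 38745), rose by 3.64 ± 0.53 (adjusted p = 0.0442), to 69.09 and 30.96 CPM from 3.5 in the remaining untreated library. Tb427_000053500:pseudogene (Chr10_3A, 875746 to 877389) rose by 3.30 ± 0.28 (adjusted p = 7.86e-04), to 173.97 and 154.21 CPM from 14.33. Tb427_110181600 (Chr11_core, 4376323 to 4376721), among the last 3 features of its unit, fell by 1.52 ± 0.22 on the log2 scale (adjusted p = 0.0442), to 51.73 and 48.16 CPM from 123.3, but the left-out library had 7.98, below both. Tb427_000019900 (BES3, 52362 to 53744) fell by 1.45 ± 0.23 (adjusted p = 0.0489), to 80.26 and 73.09 CPM from 180.11, while the left-out library, at 51.71, was also below both. The untreated side of these calls is 1 library.

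Pt-TTPY in BSF was the treatment with the highest level of features upstream in the expression sites. Those of sites other than BES1 summed to 64076.38 and 29802.21 CPM (mean 46939.3, SD 24235.5, n = 2) against 11431.48 and 24882.17 CPM without treatment, and those of BES1 to 22528.15 and 11681.44 against 4715.39 and 10314.32 CPM. Reads aligning to several sites were counted at each, so these sums are not independent. Whether sites other than BES1 responded on their own cannot be told. The median log2 fold change over the expression-site contigs was 0.45 (adjusted p = 1.62e-12, and 0.714 with an estimated correlation) and 0.17 with untreated replicate 1 left out, against 1.04 without replicate 2. Adjusted over the list alone, 29 features of these contigs were higher and none lower. The gap between both Pt-TTPY libraries was wider than the difference of their mean from the untreated mean. Subtelomeric (median −0.10), core (0.02) and unassigned (−0.12) contigs were not called (adjusted p = 0.941, 0.941 and 0.579). No single feature passed the edgeR test with or without untreated replicate 1 (798 and 624 at an unadjusted p under 0.05), and DESeq2 called 38 higher and 78 lower with it and 7 and 0 without it.

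With all libraries, few features were called for pyridostatin in BSF, with large changes and in part in runs of adjacent features. On simulated counts with the spread of this fit, 2% of log2 changes of 1 and 60% of changes of 2 were recovered. Smaller changes may therefore have gone uncalled. Of the 19 features that rose, 13 lay on subtelomeric contigs, 4 in chromosome cores and 2 on unassigned contigs, and of the 5 that fell, 4 lay on 1 subtelomeric contig, Chr11_3A. Of the 4 higher core features 3 lay in a run of 4 on Chr7_core (1762086 to 1772971), with a mean of 65.82 and 56.61 CPM per feature against 4.21 in untreated replicate 2. On Chr11_3A, a run of 7 adjacent features (32407 to 48294) had a mean of 0.77 and 0.52 CPM per feature with pyridostatin, against 17.92 in untreated replicate 2, 25.35 and 32.12 with AQ1 and 20.69 and 27.72 with Pt-TTPY. Within it Tb427_000111700 (39339 to 40016) had 1 count with pyridostatin and 150 without treatment, a ratio of 118 (95% counting interval 20.9 to 4690). Tb427_000111600 (37610 to 38050) had 3 and 229 counts, a ratio of 60.1 (20.3 to 293). In the other direction, Tb427_000837200 (unitig_50, 19853 to 21454) reached 20.9 and 18.87 CPM with pyridostatin and had no count without treatment, at least 100-fold higher (at least 39.8-fold without untreated replicate 1). Tb427_000631700:pseudogene, on an unassigned contig (93 to 1408), had 184 counts with pyridostatin and 1 without, a ratio of 234 (41.4 to 9290), and without untreated replicate 1 no count, at least 30.9-fold higher.

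With untreated replicate 1 left out, 150 features rose and 83 fell, and all 24 features called with all libraries were among them with the same direction. Of these, 71 higher and 73 lower lay in chromosome cores, 47 and 10 on subtelomeric contigs, and 31 and 0 on unassigned contigs. With all libraries, the edgeR test gave adjusted p between 0.0264 and 0.0348 for the 4 features named above, 1356 features had an unadjusted p under 0.05, and DESeq2 called 140 higher and 137 lower. No feature passed edgeR with replicate as a block (1008 at an unadjusted p under 0.05) or with either pyridostatin library left out. As groups, expression-site, subtelomeric and core contigs were not called (adjusted p = 0.564, 0.971 and 0.374), although 48 subtelomeric features were higher and 7 lower adjusted over the list alone. Unassigned contigs had a median of −0.20 (adjusted p = 0.0479, and 0.817 with an estimated correlation), and −0.28 without untreated replicate 1 (adjusted p = 0.104), and the call was also lost without untreated replicate 2 or pyridostatin replicate 2 (adjusted p = 0.349 and 0.365).

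**Figure D3:**
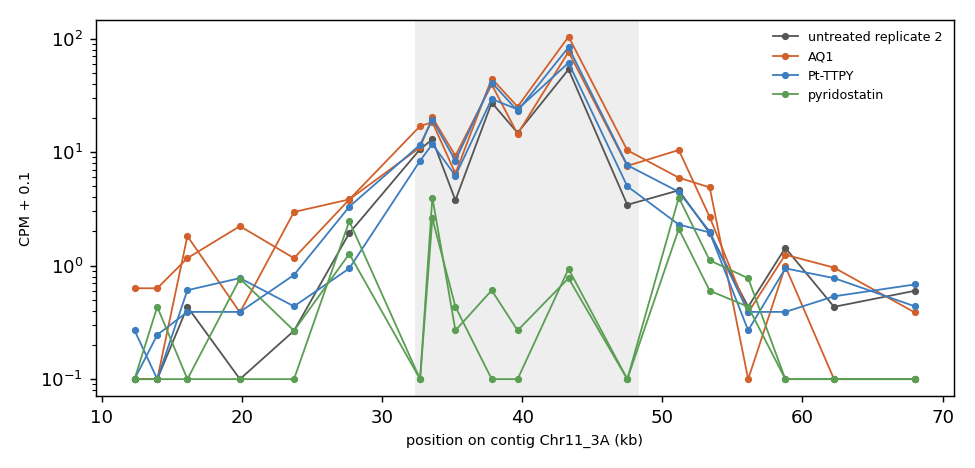
CPM (log axis, with a small offset) of single features by position on Chr11_3A, 1 line per BSF library, untreated replicate 1 left out. The run of 7 features, 32407 to 48294, is shaded, with neighbouring features on either side. The mean per feature over the run was at most 0.77 CPM in the pyridostatin libraries and 17.92 to 32.12 CPM in the other libraries drawn.

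In PCF, AQ1 went with a higher median of the weakly expressed unassigned and subtelomeric contigs and a lower one of non-triplet features, with 128 features higher and 78 lower once untreated replicate 1 was left out. Of these, 63 higher and 31 lower lay on unassigned, 18 and 15 on subtelomeric and 47 and 32 on core contigs. The median log2 fold change was 0.53 on unassigned contigs and 0.51 on subtelomeric contigs (adjusted p = 9.68e-09 and 0.00131, and 0.335 and 0.375 with an estimated correlation), and it was 0.71 for subtelomeric pseudogenes (13 of 134 higher, 4 lower, adjusted p = 5.37e-06, and 0.335 with an estimated correlation). Tb427_000668700:pseudogene (unitig_1884, 14894 to 17560) rose (adjusted p = 0.0096), to 10.87 and 12.83 CPM from 1.67. Tb427_020014300 (Chr2_core, 302234 to 303544), a copy in a tandem array, rose by 2.38 ± 0.51 (adjusted p = 0.0146), to 9.06 and 11.93 CPM from 1.85. Non-triplet features had a median of −0.76. They took 1.3% and 1.2% of the counts with AQ1 and 2.6% in untreated replicate 2, but 3.3% and 2.1% with Pt-TTPY. As this share differed between replicates of a group, the lower median is not shown to be a response to AQ1. The untreated side of all values in this paragraph is 1 library. Tb427_020029800 (Chr2_core, 742289 to 742437), 149 nt long, fell by 3.58 ± 0.37 (adjusted p = 6.39e-05), to 1.36 and 2.93 CPM from 24.09, but the left-out library had 2.94. Tb427_000595500:pseudogene (Chr9_3A, 1345246 to 1345763) fell by 3.07 ± 0.42 (adjusted p = 1.81e-04).

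With all libraries no feature passed the edgeR test for AQ1 in PCF (9567 tested, 1423 at an unadjusted p under 0.05), and DESeq2 called 56 higher and 203 lower. The median was 0.24 on unassigned contigs (adjusted p = 2.58e-05, and 0.416 with an estimated correlation), 0.20 on subtelomeric contigs (adjusted p = 0.00816, and 0.466 with an estimated correlation) and −0.01 on core contigs (adjusted p = 4.97e-05, and 0.0179 with an estimated correlation). Expression-site contigs had a median of 0.02 (adjusted p = 0.995), and no feature of these 4 regions passed when adjusted over the list alone. These shifts rested on AQ1 replicate 2, without which the median was 0.07 on unassigned contigs, −0.11 on subtelomeric contigs and 0.01 for subtelomeric pseudogenes (adjusted p = 0.155, 0.733 and 0.155), and were lost as well without untreated replicate 2 (medians 0.18, 0.10 and 0.19, adjusted p = 0.939, 0.818 and 0.362). Non-triplet features had a median of −4.04 (adjusted p = 7.11e-23, and 0.416 with an estimated correlation), a size set by untreated replicate 1.

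Pt-TTPY in PCF went with a lower fitted level of the expression-site contigs, with a median log2 fold change of −0.47 (adjusted p = 0.00106, and 0.545 with an estimated correlation) and −0.42 with untreated replicate 1 left out. At 433.97 and 465.69 CPM (mean 449.83, SD 22.43, n = 2), the upstream features of sites other than BES1 had the lowest level of the 3 treated PCF groups, but untreated cells had 155.78 and 497.12 CPM (mean 326.45), so that in CPM only untreated replicate 2 lay above Pt-TTPY. Subtelomeric, core and unassigned contigs had medians of 0.01, 0.01 and 0.03 (adjusted p = 0.988, 0.988 and 0.744). No single feature passed the edgeR test with or without untreated replicate 1 (569 and 889 at an unadjusted p under 0.05), and DESeq2 called 0 higher and 133 lower with it and none without it. The expression-site call was lost without Pt-TTPY replicate 1. Without untreated replicate 2 the test, which sets the group against all other features, pointed the other way. The medians themselves stayed between −0.42 and −0.36 with 1 library left out.

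For pyridostatin in PCF, features were called both higher and lower with untreated replicate 1 left out, most of them in chromosome cores. The untreated side of these calls is 1 library. Features higher in untreated PCF than in BSF, found with that same library, had a median log2 fold change of −0.31, against 0.06 for the rest. Whether the ligand or that library set these differences cannot be told. Tb427_070071700 (Chr7_core, 1787637 to 1788344) rose by 2.16 ± 0.52 (adjusted p = 0.048). Tb427_000497700 (Chr8_3A, 422631 to 424022) rose by 2.15 ± 0.39 (adjusted p = 0.01), to 32.24 and 22.38 CPM from 5.56, while the left-out library had 17.49. Tb427_000565900:pseudogene (Chr9_3A, 466155 to 466823) fell by 2.26 ± 0.45 (adjusted p = 0.0158) and Tb427_000595500:pseudogene, also lower with AQ1, fell by 1.98 ± 0.39 (adjusted p = 0.0151). Non-triplet features took 2.1% and 2.4% of the counts with pyridostatin and 2.6% in untreated replicate 2, a share that differed between replicates of other groups. With all libraries no feature passed the edgeR test (675 at an unadjusted p under 0.05), DESeq2 called 5 higher and 136 lower, and none of the 4 regions was called (adjusted p = 0.829 to 0.937).

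**Figure D4:**
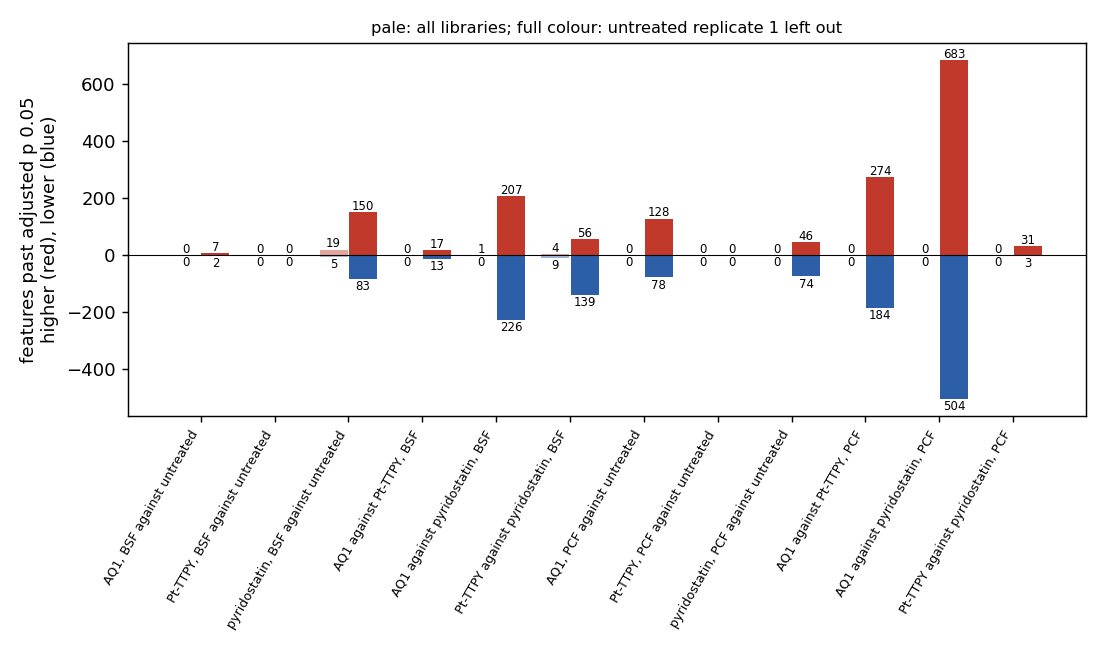
Number of features called higher or lower (adjusted p under 0.05, edgeR) in each comparison of a ligand with untreated cells or with another ligand. Bars are given with all libraries and with untreated replicate 1 left out. With all libraries, pyridostatin in BSF had 19 higher and 5 lower features.

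The ligands were compared directly within each stage, at doses that differed between them. AQ1 and Pt-TTPY in BSF differed most on the expression sites: with AQ1 the contigs were lower by a median of −0.74 (adjusted p = 3.58e-37, and 0.0825 with an estimated correlation), BES1 upstream features by −0.87 (adjusted p = 1.42e-19, and 0.0396 with an estimated correlation), while terminal features of the other sites were higher by 1.38 (adjusted p = 1.1e-09, and 0.169 with an estimated correlation), or by 0.71 without AQ1 replicate 1. Subtelomeric contigs were higher by 0.31 and unassigned contigs by 0.19 (adjusted p = 3.08e-09 and 2.46e-09, and 0.059 for both with an estimated correlation). No feature passed the edgeR test (274 at an unadjusted p under 0.05, 10 higher and 26 lower by DESeq2), and 1 expression-site feature was higher adjusted over the list alone. Without untreated replicate 1, 17 were higher and 13 lower, 10 of the lower ones on expression-site contigs. There, Tb427_000586800:pseudogene (Chr9_3A, 1067166 to 1068802) was higher with AQ1 by 3.87 ± 0.22, at 75.29 and 63.92 CPM against 4.8 and 3.55 (adjusted p = 1.28e-05). Tb427_000833400 (unitig_395) was lower with AQ1 by a log2 value of −2.28 ± 0.39 (adjusted p = 0.038).

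Against pyridostatin in BSF, few features separated the other ligands with all libraries. Tb427_000111800 (Chr11_3A, 42676 to 43947), inside the run of 7 features, was the 1 feature called between AQ1 and pyridostatin, at 103.82 and 76.25 CPM with AQ1 against 0.67 and 0.83 (log2 fold change 6.65 ± 0.51, adjusted p = 0.0251, 737 at an unadjusted p under 0.05). Between Pt-TTPY and pyridostatin 4 features were higher and 9 lower with Pt-TTPY (423 at an unadjusted p under 0.05), and Tb427_000477900 (Chr7_5A, 695556 to 697157) had 300 counts with pyridostatin and 2 with Pt-TTPY, a ratio of 161 (44.2 to 1340). DESeq2 called 25 higher and 55 lower with AQ1, and 9 higher and 51 lower with Pt-TTPY. The counts rose to 207 and 226 for AQ1 and to 56 and 139 for Pt-TTPY without untreated replicate 1. Core tandem arrays were lower than with pyridostatin, by −0.47 with AQ1 and −0.22 with Pt-TTPY (adjusted p = 6.52e-07 and 6.63e-05, and 0.183 and 0.338 with an estimated correlation), the latter between −0.05 without Pt-TTPY replicate 1 and −0.40 without replicate 2. Expression-site contigs were at −0.39 with AQ1 and 0.33 with Pt-TTPY (adjusted p = 5.77e-04 and 2.85e-10, and 0.488 and 0.338 with an estimated correlation), the former lost without AQ1 replicate 2 (adjusted p = 0.277) and the latter 0.20 without Pt-TTPY replicate 1. For features not called, the difference between any 2 ligands in BSF was known to a median 95% half-width of 0.823 to 0.826, and of 0.478 to 0.485 without untreated replicate 1.

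In PCF, AQ1 differed from both other ligands by the place of a gene in its transcription unit. The first 3 features of the core units were higher with AQ1 by a median of 0.31 against pyridostatin and 0.23 against Pt-TTPY (adjusted p = 1.15e-07 and 9.06e-07, and 0.326 and 0.214 with an estimated correlation). Against pyridostatin the medians fell from 0.31 over features 1 to 3 through 0.19, 0.07 and −0.01 to −0.14 beyond the 40th feature, and the start exceeded the late part in 94 of 106 units. The count of units is not particular to AQ1. For Pt-TTPY against pyridostatin it was 82 of 106 in PCF and 79 of 108 in BSF, and for AQ1 against Pt-TTPY in BSF 26 of 108. The median difference over units was 0.41 for AQ1 against pyridostatin in PCF and 0.097 for Pt-TTPY against pyridostatin. With untreated replicate 1 left out, 71 of 334 of these first features were higher and 6 lower against pyridostatin, and 23 and 2 against Pt-TTPY. The last 3 features were not called against either (adjusted p = 0.511 and 0.532). Subtelomeric pseudogenes were higher with AQ1 by 0.39 than with Pt-TTPY and by 0.27 than with pyridostatin (adjusted p = 1.82e-07 and 3.45e-06, and 0.168 and 0.253 with an estimated correlation), the former 0.14 without AQ1 replicate 2 and 0.72 without Pt-TTPY replicate 1, the latter lost without AQ1 replicate 2 (adjusted p = 0.213) and 0.50 without pyridostatin replicate 1.

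**Figure D5:**
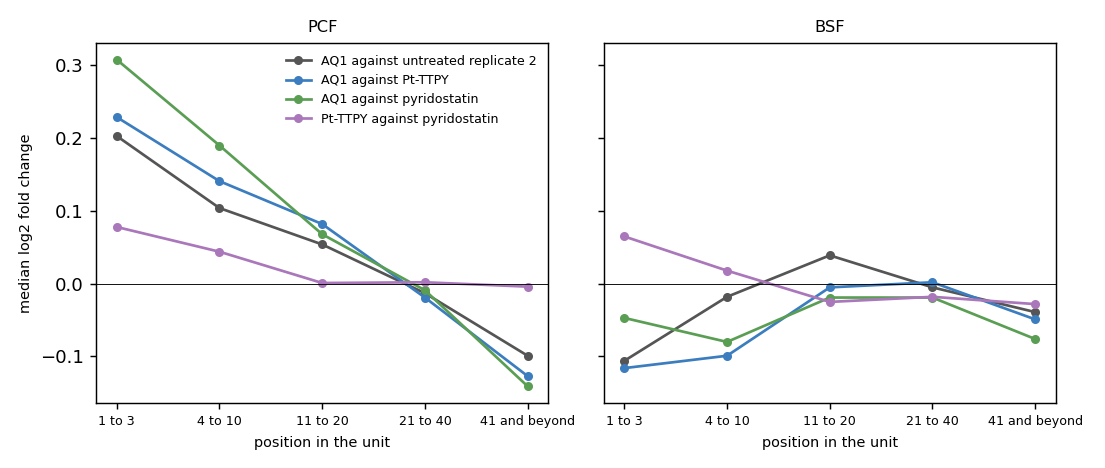
Median log2 fold change of core features in PCF and BSF by position in the transcription unit, with untreated replicate 1 left out. Lines show AQ1 against untreated replicate 2, Pt-TTPY and pyridostatin, and Pt-TTPY against pyridostatin. With all libraries, the PCF median of AQ1 against pyridostatin fell from 0.31 in features 1 to 3 to −0.14 beyond the 40th.

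No feature passed the edgeR test between ligands in PCF with all libraries, with 319, 556 and 68 at an unadjusted p under 0.05 for AQ1 against Pt-TTPY, AQ1 against pyridostatin and Pt-TTPY against pyridostatin. DESeq2 called 2 higher and 1 lower, 10 and 1, and 0 and 0. Leaving out untreated replicate 1, edgeR called 274 higher and 184 lower, 683 and 504, and 31 and 3. Tb427_020029800 was lower with AQ1 than with Pt-TTPY by −3.26 ± 0.34 (adjusted p = 3.62e-06), and Tb427_000668700:pseudogene was higher by 2.96 ± 0.44 (adjusted p = 3.78e-04). Between Pt-TTPY and pyridostatin, Tb427_110132500 (Chr11_core, 3166747 to 3173256) was higher with Pt-TTPY by 1.67 ± 0.24 (adjusted p = 5.98e-04) and the BES1 terminal feature lower by −0.97 ± 0.19 (adjusted p = 0.0293). Expression-site contigs were lower with Pt-TTPY than with pyridostatin by a median of −0.42 (−0.20 without pyridostatin replicate 1), and higher with AQ1 than with Pt-TTPY by 0.33 (adjusted p = 2.99e-11 and 2.41e-05, and 0.108 and 0.178 with an estimated correlation). The median 95% half-width of a difference was 0.804 to 0.809, and 0.417 to 0.424 without untreated replicate 1.

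The responses of the stages were compared by their interaction. No feature passed the edgeR test for AQ1, Pt-TTPY or pyridostatin (492, 218 and 531 at an unadjusted p under 0.05), and DESeq2 called 1 higher and 2 lower, 0 and 20, and 5 and 5. When untreated replicate 1 of both stages was left out, 13 were higher and 2 lower for pyridostatin and none for AQ1 and Pt-TTPY (1162 and 521 at an unadjusted p under 0.05, and 3 and 2 called by DESeq2). Among the regions, the Pt-TTPY response of the expression-site contigs was lower in PCF than in BSF by a median of −1.05 (adjusted p = 2.19e-37, 0.0191 with an estimated correlation and 0.0718 with fry), with 28 features lower adjusted over the list alone. It was −0.92 with untreated replicate 1 left out (0.396 with an estimated correlation), and with 1 library left out it ranged from −1.82 (without BSF untreated replicate 2) to −0.63 (without PCF untreated replicate 2). For the AQ1 response none of the 4 regions was called (adjusted p = 0.112 to 0.913), which does not show that the stages responded alike. The median 95% half-width of this difference for single features was 1.168. Expression-site contigs held little signal in PCF, at 2.59 and 2.85 CPM per feature with Pt-TTPY and 0.84 and 3.10 without treatment. The PCF side of their Pt-TTPY difference therefore rests on low counts. Doses and cell lines differed between the stages.

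The log2 fold changes of different ligands against the same untreated libraries were correlated across features, which are not independent replicates. Pearson's r was 0.747 to 0.843 in BSF and 0.854 to 0.924 in PCF, and simulations of unchanged groups that share the untreated libraries gave 0.887 to 0.895 and 0.901 to 0.905. The covariances were 0.516 to 0.571 in BSF (simulated 0.354) and 0.569 to 0.669 in PCF (simulated 0.345 to 0.346). Without untreated replicate 1 they were 0.215 to 0.296 in BSF (simulated 0.09) and 0.188 to 0.249 in PCF (simulated 0.069 to 0.07), and among features with a mean of at least 10 CPM 0.097 to 0.15 (simulated 0.057) and 0.056 to 0.1 (simulated 0.042). The simulations drew each feature independently, without trends that run through a whole library. A covariance above the simulated one therefore does not show a shared response. Between stages, which share no library, the response to AQ1, Pt-TTPY and pyridostatin was correlated at r = 0.78, 0.839 and 0.756, and at 0.183, 0.179 and 0.15 with untreated replicate 1 of both stages left out. Simulated unchanged groups yield almost no calls, so their overlap of calls is small in any case and cannot decide whether a response was shared. Overlaps were counted without untreated replicate 1. With that library left out, AQ1 and pyridostatin in PCF shared 7 higher and 26 lower features, against 0.02 and 0.01 in simulations of unchanged groups with that common untreated library and 0.6 and 0.59 by independence, which ignores it. In BSF they shared 5 and 1 (0.04 and 0.01 simulated, 0.1 and 0.02 by independence).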

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

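The tests of explanations weighed here were chosen after the result was seen, except that pyridostatin lowers the Chr11_3A run in either stage, and expression level as the source of the unit-position trend, whose tests were set before. The differences between stages were tested by the interaction, as PCF minus BSF, and doses and cell lines differ between the stages. The interaction and the contig groups were fixed before the data were examined, and the smaller groups of features were made afterwards.

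The Pt-TTPY response of the expression-site contigs differed by −1.047 (adjusted p = 2.19e-37, and 0.0191 with an estimated correlation), with medians of 0.45 in BSF and −0.47 in PCF. It differed by −0.756 for BES1 upstream features (adjusted p = 1.5e-06, and 0.0386 with an estimated correlation) and by −1.112 for the upstream features of the other expression sites (adjusted p = 8.57e-40, and 0.0191 with an estimated correlation). Reads aligning to several sites were counted at each, so these upstream results are not independent. The stage medians came from separate fits with different tested features. In PCF the expression-site contigs held 2.59 and 2.85 CPM per feature with Pt-TTPY, against 702.93 and 756.37 in BSF. With untreated replicate 1 of both stages left out, the 3 values were −0.925, −1.188 and −0.995 (adjusted p = 1.18e-17, 4.63e-06 and 9.19e-18, and 0.396 for each with an estimated correlation). None of the 3 was called with fry (adjusted p = 0.0718, 0.0971 and 0.0718). With 1 library left out, they ranged from −1.82 (without BSF untreated replicate 2) to −0.631 (PCF untreated replicate 2), from −1.48 (PCF Pt-TTPY replicate 2) to −0.355 (PCF untreated replicate 2, call lost, adjusted p = 0.122) and from −1.933 (PCF Pt-TTPY replicate 2) to −0.9. Subtelomeric pseudogenes differed by −0.338 (adjusted p = 0.0474, and 0.703 with an estimated correlation), although the medians of the stage fits, 0.05 in BSF and 0.07 in PCF, did not run in that direction. They differed by −0.01 without untreated replicate 1, and with 1 library left out the call was kept only without PCF untreated replicate 2 or PCF Pt-TTPY replicate 1.

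The AQ1 response of the first 3 features of a core unit differed by 0.384 (adjusted p = 7.89e-07, and 0.358 with an estimated correlation), with medians of −0.02 in BSF and 0.37 in PCF, and by 0.284 without untreated replicate 1 of both stages (adjusted p = 7.87e-05, and 0.483 with an estimated correlation). With 1 library left out it ranged from 0.126 (without BSF untreated replicate 2) to 0.737 (PCF untreated replicate 2). That of non-triplet features differed by −0.408 (adjusted p = 0.0461, and 0.927 with an estimated correlation), and by −1.252 without these libraries (adjusted p = 1.33e-15, and 0.355 with an estimated correlation). The pyridostatin response differed by 0.214 on unassigned contigs (adjusted p = 0.0197, and 0.458 with an estimated correlation) and by −0.358 for upstream features of the other expression sites (adjusted p = 0.0447, and 0.675 with an estimated correlation). It differed by −0.859 for non-triplet features (adjusted p = 6.86e-07, and 0.671 with an estimated correlation) and by −0.397 for core tandem arrays (adjusted p = 2.08e-05, and 0.431 with an estimated correlation). Without untreated replicate 1 these 4 values were 0.376, −0.241, −1.315 and −0.388 (adjusted p = 2.41e-04, 0.549, 9.94e-14 and 9.61e-05), so the call of the upstream features was lost, and none was called with an estimated correlation (adjusted p = 0.468, 0.932, 0.468 and 0.468). With 1 library left out they ranged from 0.037 to 0.431, −0.715 to −0.179, −2.773 to 1.286 and −0.81 to −0.065, and each lost its call without at least 1 of the untreated libraries.

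Untreated replicate 1 of both stages stood apart from the other 14 libraries. The non-triplet features were not the whole cause, since without them the higher rank correlation of the untreated pairs was 0.741, against 0.956 in the lowest treated group. A swap of the stage labels is excluded, since BSF untreated replicate 1 had 23362.26 CPM on expression-site contigs, against at most 771.66 in PCF. A difference in preparation or handling shared by both libraries is a candidate explanation: replicate 1 minus replicate 2 correlated across features at 0.868 between the stages, against at most 0.318 for the other pairs of groups of different stage. Both libraries share a title prefix that the others lack, and no biological explanation was tested.

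The run of 7 features on Chr11_3A was lower with pyridostatin in BSF, and 3 further runs, on Chr4_3A, Chr7_core and Chr8_5A, were higher by 10.5-fold, 8.68-fold and 8.17-fold over all features between their ends. The 18 pairs of BSF libraries from different groups and the 2 other replicate pairs gave 0 such runs, against 4 for the pyridostatin pair. All 21 pairs of PCF libraries gave 0 as well, replicate pairs of each ligand included. A run asked both libraries of a pair to lie 3-fold beyond every other library of the stage. For pairs of different groups those others held a replicate of at least 1 of the pair, so such pairs could hardly give a run and say little. The replicate pairs remain too few to exclude chance. Counting error is excluded for Chr11_3A, with at most 32 counts where at least 744.3 were predicted from the other libraries. Whether pyridostatin lowers this run in either stage cannot be told apart from a cause private to these BSF cultures, since PCF barely expressed it (at most 0.614 CPM per feature with pyridostatin, and as low as 0.162 with another ligand). A shared culture or subclone behind both pyridostatin libraries stays open, since the labels do not say that they were separate.

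With AQ1 in PCF, features at the start of core units were higher than those further along, relative to pyridostatin. Coding length is not the source, as the slope per doubling of position was −0.0727 ± 0.0028 with length as a term, and neither is expression level (−0.0724 ± 0.0029 with both as terms), though these errors treat features as independent. The pattern was in both AQ1 libraries, the lower at 0.186 against −0.035 in the highest of 5 other PCF libraries. Beyond the 10th feature the slope was still −0.0669 ± 0.0047, which is consistent with a gradual fall along the whole unit. An effect of AQ1 on transcription or RNA along the unit may therefore be a hypothesis, found and tested on the same data, and a difference in RNA quality between groups was not tested. The libraries also differed by a trend with length. The difference of AQ1 from pyridostatin correlated with log2 length across these features at r = −0.385. By library, r was −0.437 and −0.051 with AQ1, and 0.396 and 0.26 with pyridostatin.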

How the results depend on the processing

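The alternatives with untreated replicate 1 left out of comparisons between ligands, between stages or of interactions, and those that combine it with DESeq2 or relative log expression (RLE) size factors, were chosen after the data were seen, as were the smaller groups of features. Where a value changed, the cause was not tested unless named. The 16 counts of changed features stayed within 1.5 times with a filter of 5 CPM in 2 libraries (16 of 16), RLE size factors (15), leaving out non-triplet and expression-site terminal features (15) and a replicate block (13). Most of these counts were 0 with all libraries, and a count that stays at 0 says little of stability. The replicate block took the BSF counts of 24, 1 and 13 to 0. Of the 13 named features called with all libraries, 13 kept their call and direction with DESeq2 and RLE size factors, 5 with only the groups compared and 4 with a replicate block, and none reversed. Of 94 called groups, 91 kept their call with RLE size factors, 92 with a replicate block, 18 with an estimated correlation and 9 with fry. Of 67 called groups in comparisons between ligands, between stages or of interactions, 62 kept their call with untreated replicate 1 left out. Groups called for a ligand against untreated cells are not among the 67. Contrasts between ligands hold no untreated library, so this count says little on how far the calls rest on it. The list of features with a G-quadruplex motif and its alternatives, and leaving out ribosomal, transfer and variant surface glycoprotein genes by name, could not be run for want of sequence and names.

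DESeq2 called 75, 116 and 277 features for AQ1, Pt-TTPY and pyridostatin in BSF and 259, 133 and 141 in PCF. Between ligands it called 36 (AQ1 against Pt-TTPY), 80 (AQ1 against pyridostatin) and 60 (Pt-TTPY against pyridostatin) in BSF and 3 and 11 for the first pairs in PCF. For the interactions with stage it called 3, 20 and 10. With untreated replicate 1 left out, DESeq2 called 51, 7 and 284 in BSF, 113 for AQ1 and 89 for pyridostatin in PCF, 101, 403 and 167 between ligands in BSF, 256, 650 and 24 in PCF, and 3, 2 and 69 for the interactions.

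Without untreated replicate 1, edgeR called 30, 433 and 195 features between ligands in BSF, 458, 1187 and 34 in PCF, 3273 between stages and 15 for the pyridostatin interaction. The spread among replicates was smaller without this library, which by construction lets more features pass. RLE size factors in the same fits gave 7 for AQ1 and 189 for pyridostatin in BSF, 200 and 110 in PCF, 29, 432 and 189 between ligands in BSF, 452, 1170 and 33 in PCF, 3120 between stages and 16 for the pyridostatin interaction. They moved the balance of the stage comparison from 1583 higher and 1690 lower to 1249 and 1871. With all libraries, RLE gave 3 between AQ1 and pyridostatin in BSF, as did leaving out non-triplet and terminal features (3).

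Without a count filter edgeR called 7 for AQ1 and 80 for pyridostatin in BSF, 29 for AQ1 in PCF, 2, 39 and 46 between ligands in BSF, 1 and 23 for AQ1 against Pt-TTPY and pyridostatin in PCF, and 7 for the Pt-TTPY interaction. With only the groups compared it called 0 for pyridostatin in BSF, 4, 833 and 286 between ligands in BSF, 378, 1059 and 54 in PCF and 147 between stages. Such fits between ligands hold no untreated library. With all 16 libraries in 1 fit it called 1 and 2 for AQ1 against Pt-TTPY and pyridostatin in PCF.

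The replicate numbers came from the titles, and whether they pair libraries was checked by the correlation across features of replicate 1 minus replicate 2 between groups of a stage. Over 12 such pairs of groups it lay between −0.565 and 0.337, with 4 over 0.1 and 7 under 0, so the numbers were not used as pairs. With the replicate block, edgeR called 0 features for pyridostatin in BSF, 0 between AQ1 and pyridostatin and 0 between Pt-TTPY and pyridostatin in BSF.

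Leaving out each library of the groups compared in turn, with the lone library assumed to vary like the other groups, gave 0 to 4151, 0 to 4924 and 0 to 4669 changed features for AQ1, Pt-TTPY and pyridostatin in BSF and 0 to 5395, 0 to 4619 and 0 to 4270 in PCF. The high end came each time without untreated replicate 2, when replicate 1 alone stood for untreated cells. Between AQ1 and pyridostatin and between Pt-TTPY and pyridostatin in BSF each fit without 1 library of the groups compared gave 0 with edgeR (236 to 384 and 175 to 293 at an unadjusted p under 0.05), unlike the fits without untreated replicate 1 given above. The range was 1600 to 2855 between stages, 0 to 16 for the Pt-TTPY interaction (16 without BSF Pt-TTPY replicate 2) and 0 to 1 for the pyridostatin interaction.

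Of 416 group values with 1 library left out, 336 kept their call, 67 lost it and 13 reversed. Non-triplet features ranged from −3.43 to −0.053 for AQ1, −2.51 to 0.30 for Pt-TTPY and −1.77 to 0.89 for pyridostatin in BSF, from −1.38 to 1.87 between stages, and from −2.08 to 1.91 and −2.77 to 1.29 for the AQ1 and pyridostatin interactions. In BSF, intact subtelomeric features ranged from −0.15 to 0.59 for AQ1 and the terminal features of other expression sites from −0.12 to 2.19 for Pt-TTPY. In PCF, subtelomeric contigs ranged from −0.11 to 0.51 for AQ1 and expression-site contigs from −0.42 to −0.36 for Pt-TTPY. The Pt-TTPY interaction of subtelomeric pseudogenes ranged from −0.65 to 0.

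With untreated replicate 1 left out, the correlation of ligand responses was 0.673, 0.586 and 0.603 in BSF and 0.599, 0.562 and 0.796 in PCF, and between stages 0.183, 0.179 and 0.15. Unchanged groups that share the untreated library gave 0.667, 0.664 and 0.681 in BSF and 0.659, 0.647 and 0.651 in PCF, so that only Pt-TTPY and pyridostatin in PCF lay clearly above them. Among features with a mean of at least 10 CPM, that of AQ1 and pyridostatin in BSF was 0.845 with all libraries (simulated 0.918). Depth limits features with few counts. The filter left out those that were low in all or nearly all libraries, but kept some that had no count in a whole group.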

Other observations

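The tests in this part were chosen after the data were seen. A pair of interleaved tandem arrays on the core of chromosome 2 (293224 to 325511 and 295145 to 328365, copies of 378 and 1311 nt, 20 features) was expressed mainly in BSF, and some copies were higher with AQ1 in PCF. All 10 copies of each were lower in untreated PCF than in BSF, with medians of −5.12 and −5.69. In PCF the mean level per copy was 8.57 and 8.49 CPM with AQ1, against 1.08 and 1.76 without treatment, 3.01 and 2.46 with Pt-TTPY and 4.44 and 4.36 with pyridostatin. With untreated replicate 1 left out, 4 of the 10 shorter and 7 of the 10 longer copies rose with AQ1, and none passed the edgeR test with all libraries (medians 1.87 and 1.74). Copies share reads and are not independent. On chromosome 11 in PCF, also with that library left out (none with all libraries), 8 of 8 copies of an array (2458081 to 2477381) were lower with AQ1 than with Pt-TTPY (−0.95 ± 0.18 for the first copy, adjusted p = 0.00414) and 8 of 8 were higher with Pt-TTPY than with pyridostatin (0.92 ± 0.19, adjusted p = 0.0293).

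A family of 21 non-triplet features of 169 nt had a mean level of 158 and 133 CPM per feature with AQ1 in PCF and 187 and 232 with pyridostatin, against 519 and 454 with Pt-TTPY and 418 in untreated replicate 2. In BSF the level was 51.3 and 45.0 CPM with pyridostatin, 135 and 108 with AQ1, 108 and 284 with Pt-TTPY and 119 in untreated replicate 2. Untreated replicate 1 had 4191 in PCF and 1807 in BSF. The share of counts on non-triplet features as a whole differed between replicates of a group, so these levels are not shown to be a response to a ligand. In the fits without untreated replicate 1, among features higher in untreated PCF than BSF the median difference of AQ1 from pyridostatin in PCF was 0.23, against −0.05 for the rest, and 275 of the 683 features higher with AQ1 were among them (109.9 by independence). In BSF, features higher in untreated BSF were more frequent than by independence among those higher with AQ1 than with pyridostatin, and also among those lower. Their median difference of AQ1 from pyridostatin was 0.20, against −0.03 for the rest. Independence ignores that features higher in a stage are better expressed there and easier to call, and with all libraries 0 and 1 features were higher with AQ1 (edgeR).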
